A study of Homo sapiens with 8 samples.

How the data were processed

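RNA was sequenced from 8 libraries labelled as HSC3, an established human oral squamous cell carcinoma line. Per the labels, 4 libraries received an siRNA against COL1A1 and 4 a non-targeting siRNA, at 100 pmol with a lipid reagent, and cells were collected after 48 hours. The labels name the molecule as polyA RNA, while the labels' extraction protocol describes ribosomal RNA depletion of total RNA. RN7SL1 and RMRP, RNAs without a polyA tail, stood at 5508 to 147900 and 3446 to 7976 CPM across the 8 libraries. These levels argue against polyA selection, as far as these genes show. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, whose source is unknown. Within the control label, skeletal muscle genes took 0.035% to 17.86% of counts, which argues against repeat libraries of a single culture.

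The deposited table holds whole-number read counts per gene, with no normalisation by the authors. Per the submitters' processing notes, STAR, featureCounts from Subread and the hg38 build were used; versions, annotation and strand setting are not given in the sources used here. The column names call the treated libraries a knockout where the titles call them a knockdown, and each column was matched to a library by group and number. The table has 63241 gene rows, of which 17219 hold 0 in all 8 libraries. A gene symbol was matched to 62666 rows by Ensembl identifier and 575 rows had none. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Counts of near-identical family members (the SPRR2, NBPF, KRT6 and RN7SL genes among them) are uncertain.

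Total counts ran from 30684584 to 61795990 per library, a ratio of 2.01. Shares of counts per library have Wilson 95% intervals no wider than 0.015 percentage points on either side. These intervals cover counting error only.

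Knockdown was compared with control by edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. CPM values use TMM-scaled library sizes unless given as CPM of all counts. The design had an intercept and the group. The filter kept 21192 genes, which hold at least 94.4% of each library's counts, and TMM factors ran from 0.75 to 1.19. The 24 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, an estimated correlation, and the fry rotation test. The rule named COL1A1, the called genes with the largest change whose groups do not overlap or, with none called, the 5 of smallest p in each direction, the called members or the 2 most abundant members of each list, and 10 usual markers of epithelial-mesenchymal transition (EMT). Genes picked by change or by p also needed a mean log2 CPM of at least 1. They needed a gene symbol as well, and pseudogenes and clone-type names were left out. Another 4 lists (skeletal muscle contractile, salivary gland secretory, smooth muscle and adipocyte genes) were written after the counts had been seen. Comparisons of single values used exact two-sided permutation tests over the 70 assignments of 8 libraries, whose smallest p is 0.0286, in scipy 1.17.1. Principal components used log2(CPM + 1) of the 500 most variable genes.

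The tests were checked on simulated counts for this comparison, with the 21192 genes and their means, and 50 genes changed at each fold. The changed genes were drawn only from genes above a minimum mean CPM, so the shares recovered do not cover genes of lower level. Genes changed 2-fold or 16-fold were all raised in knockdown, and those changed 4-fold or 64-fold were all lowered. With a biological coefficient of variation of 0.2, edgeR recovered 90% of genes changed 2-fold and 100% of those changed 4-fold, and called 13 of 20992 unchanged genes. With the spread of the real libraries it recovered 0% at 2-fold, 2% at 4-fold, 58% at 16-fold and 86% at 64-fold, and called 3 unchanged genes, while DESeq2 called 90. Of the genes changed at these folds DESeq2 called 2%, 32%, 94% and 98%, with the direction not checked. With the coefficient of 0.2, a simulated list raised 4-fold was called by camera and 0 of 20 unchanged lists were. Lists were not simulated with the spread of the real libraries. The simulated genes varied independently, and on the real counts camera called a median of 11 of the 24 lists over the 35 splits of the libraries into 4 and 4 (5 to 19), so the simulation does not give its error rate on these data.

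Alternatives were DESeq2 1.42.0, limma-voom, RLE factors, library totals without TMM, leaving out genes over 1% of counts, other filters on low counts, a replicate block, leaving out each library, other set tests, and other gene sets or pseudocounts for the components. Added after seeing the data were fits without libraries with over 1% of counts in the salivary list, without those over 1% in the skeletal muscle or salivary list, and with the muscle share as a covariate. Levels of sex-linked genes are not reported, and some genes that the rule names are not reported here.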

Results

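The series measured RNA in libraries labelled as HSC3 cells, a line derived from an oral squamous cell carcinoma; by their labels, 4 were transfected with an siRNA against COL1A1 and 4 with a non-targeting siRNA. Its title puts the question of whether loss of COL1A1 reduces EMT, migration and invasion. The libraries labelled knockdown held 60200909, 30684584, 36458483 and 36485435 counts in replicates 1 to 4, and those labelled control held 36786421, 61795990, 32242870 and 52018756. Because the target gene did not follow the labels in every library, groups are called by their labels throughout.

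COL1A1 encodes the alpha 1 chain of type I collagen and lies on the minus strand of chromosome 17 from 50183289 to 50201632 (GRCh38, the same assembly as hg38; ENSG00000108821.14). Its level was 273.7 ± 168.2 CPM (SD, n = 4) in the libraries labelled knockdown and 2149 ± 3542 CPM (SD, n = 4) in those labelled control. In replicates 1 to 4, COL1A1 stood at 434.7, 109.8, 402 and 148.5 CPM under the knockdown label and at 103.1, 7452, 401.3 and 641 CPM under the control label. The groups overlapped, and control 1 lay below every library labelled knockdown. The fitted log2 fold change was -2.97 (SE 1.30), with an edgeR p of 0.0484 unadjusted and 0.981 adjusted over all tested genes. An exact two-sided permutation test of the 8 CPM values gave p = 0.371. Control 2 set most of that fold, since the log2 fold change was -0.48 without it (SE 0.758, edgeR adjusted p = 0.989). The ratio of COL1A1 to COL1A2, the partner chain of type I collagen, ranged from 0.59 to 2.37 in knockdown and from 0.42 to 1.6 in control. The log2 ratio differed by 0.33 between groups (permutation interval -1.42 to 2.5, exact permutation p = 0.543).

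**Figure D1:**
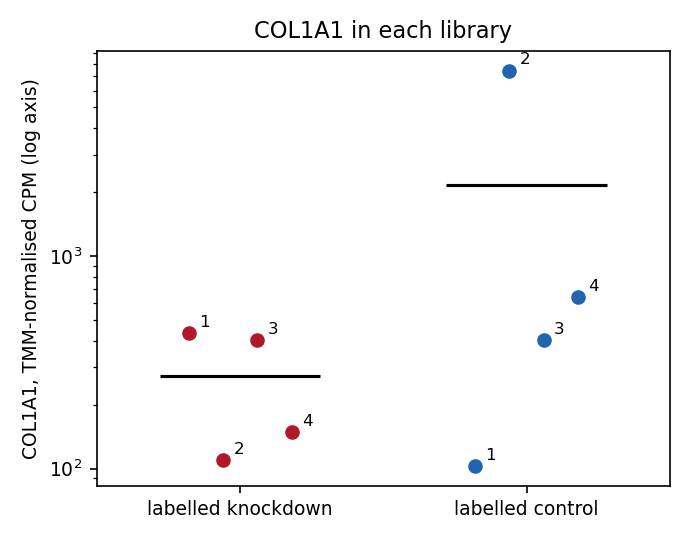
COL1A1 in TMM-normalised CPM on a log axis for each library, by label; numbers are replicates and bars are arithmetic means of 4 libraries. The libraries labelled knockdown lie between 109.8 and 434.7 CPM, and those labelled control between 103.1 and 7452 CPM.

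The libraries differed widely in transcripts of several cell types, within each label. TTN, the giant sarcomere protein of striated muscle, took 97600 CPM of all counts in control 3 and 96300 in control 1, against 17.4 in knockdown 3 and 21.2 in control 4. Skeletal muscle contractile genes together took 17.86% of counts in control 1 (Wilson 95% interval 17.85 to 17.87) and 17.17% in control 3, 5.55% in knockdown 4, 4.31% in knockdown 2, and between 0.02% and 0.53% in the other 4 libraries. Salivary gland secretory genes took 22.4% of counts in control 1 and 15.2% in knockdown 2, and at most 0.052% in the other 6. LCN1, a tear and saliva lipocalin, reached 66000 CPM of all counts in control 1, and MUC5B, a gel-forming mucin, 60200 in knockdown 2. Neither share differed between labels by more than the spread between libraries (exact permutation p = 0.514 for muscle and 0.914 for salivary genes; adjusted p = 0.8 and 0.914 over 28 lists). Both lists were written after the counts had been seen. The pan-leukocyte gene PTPRC was between 11 and 75.9 CPM of all counts in the 8 libraries, the endothelial gene PECAM1 between 32.0 and 156, and the fibroblast proteoglycan DCN between 27.5 and 1270.

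**Figure D2:**
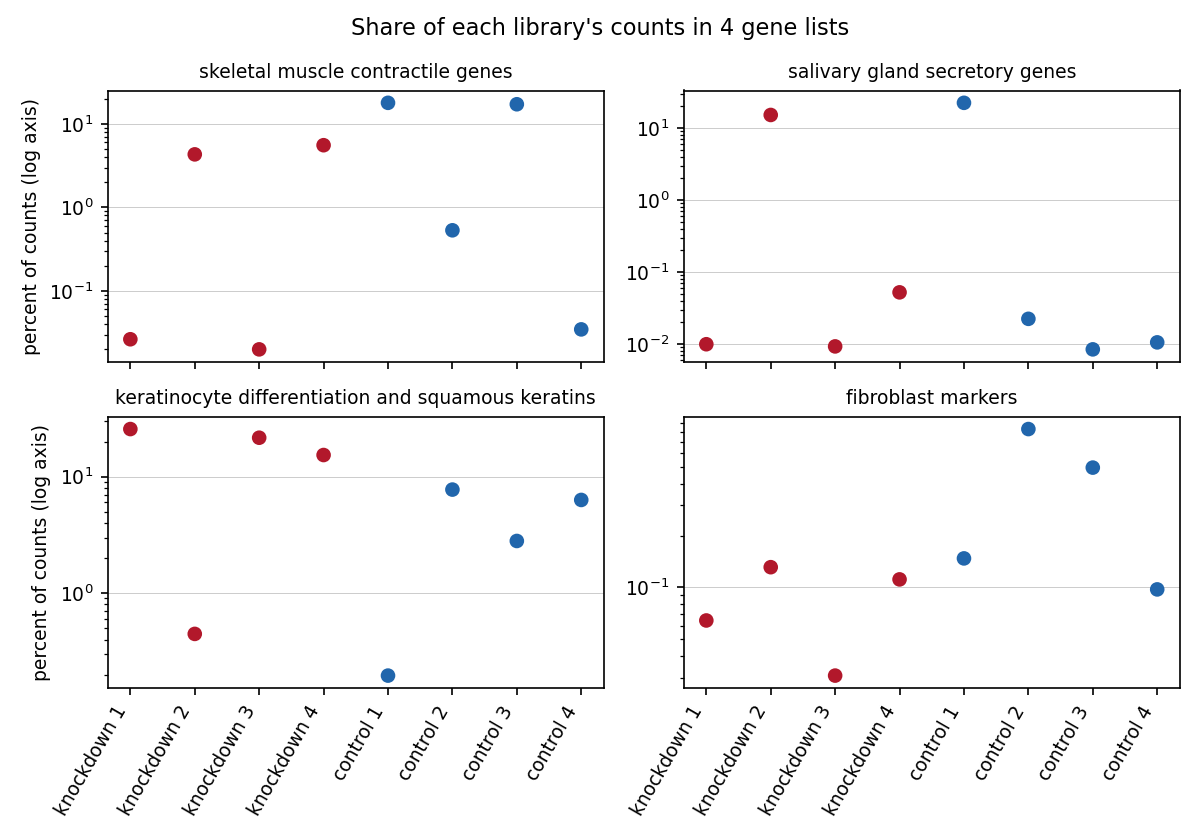
Percent of each library's counts in 4 gene lists, on log axes, with libraries labelled knockdown in red and control in blue. Muscle genes exceed 1% of counts in 2 libraries of each label, and salivary genes in 1 library of each.

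Squamous keratins also varied. Keratinocyte differentiation genes took 25.6% of counts in knockdown 1, 21.6% in knockdown 3 and 15.3% in knockdown 4, but 0.447% in knockdown 2, and from 0.196% to 7.74% in the libraries labelled control (exact permutation p = 0.371, adjusted p = 0.659). KRT6A, a keratin of stressed and proliferating squamous epithelium, ran from 10.4 CPM of all counts in control 1 to 42500 in knockdown 1, and KRT14, a basal keratin, from 281 to 32400.

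The first principal component took 66.1% of the variance and the second 16.2%. On the first, the libraries labelled knockdown scored 62.9, -58.8, 65.5 and -1.8, and those labelled control -85.6, 16.1, -39.6 and 41.4. Spearman correlations had a median of 0.86 within labels and 0.86 between them, and 3 of 8 libraries correlated best with a library of their own label.

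**Figure D3:**
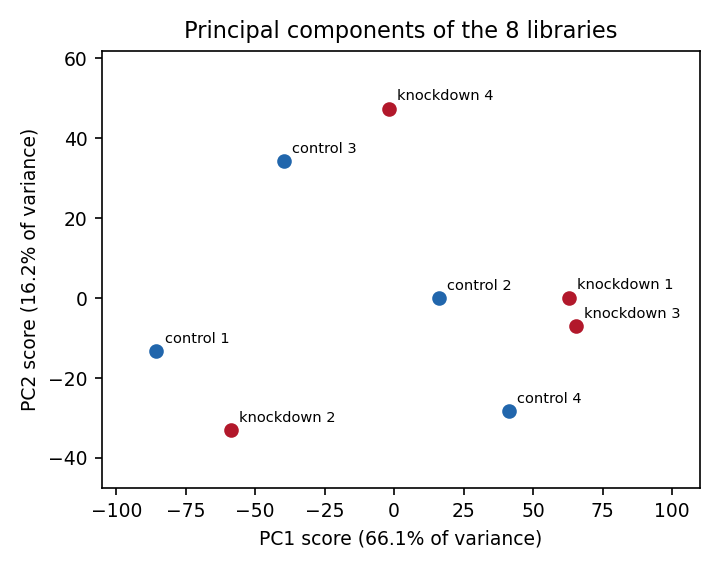
Scores of the 8 libraries on the first and second principal components of log2(CPM + 1) of the 500 most variable genes, with libraries labelled knockdown in red and control in blue. Both labels spread along the first component, from -58.8 to 65.5 in knockdown and from -85.6 to 41.4 in control.

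No gene passed the threshold between the labels: edgeR called 0 of 21192 genes, and 0 at 2-fold. The smallest adjusted p was 0.981. At an unadjusted p under 0.05 stood 1013 genes, 4.78% of those tested, of which 615 were higher and 398 lower in knockdown. The groups did not overlap for 538 genes, or 2.54%, where chance gives 2.86%. limma-voom called 0 genes and DESeq2 called 146, of which 129 were higher in knockdown and 44 had been removed by the filter of the edgeR fit. Without knockdown 2, edgeR called 1 gene, SPRR2F (adjusted p = 0.0332), chosen here after its values were seen. The filter had removed it from the fit of all 8 libraries, so it was first tested there, and with no filter edgeR called 0 genes. This cornified envelope gene stood at 65.4, 0.228, 79.9 and 59.9 CPM of all counts in knockdown and at no more than 0.124 in control.

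Only genes with a gene symbol and a mean log2 CPM of at least 1 were ranked here, and some genes left out by this had smaller p. Ranked genes with the smallest p and no overlap between labels included TM7SF2, a sterol reductase of cholesterol synthesis, at 73.65 ± 37.9 CPM in knockdown and 8.82 ± 2.30 in control (SD, n = 4 each), with a log2 fold change of 3.06 (SE 0.502). ELF3, an epithelial transcription factor, was at 112.2 ± 33.5 and 35.41 ± 6.70 CPM, and ATP6V1C2, a proton pump subunit, at 13.83 ± 10.43 and 0.984 ± 0.562. NBPF26, of a family of near-identical copies, was at 40.05 ± 9.01 and 12.74 ± 3.11 CPM. SPRR2E, another cornified envelope gene with close paralogs, was at 836.8 ± 597.8 and 0.721 ± 0.717 CPM, with 2.48 CPM in knockdown 2. In the other direction, CSF3R, the receptor of granulocyte colony-stimulating factor, was at 1.46 ± 0.541 CPM in knockdown and 10.08 ± 5.84 in control. PRKAB2, a subunit of AMP-activated kinase, was at 40.6 ± 0.877 and 103.8 ± 43.45 CPM (153 and 127.4 in controls 1 and 3, the libraries with the most muscle transcripts), PGM2L1 at 9.82 ± 4.30 and 34.46 ± 13.21, ST3GAL2 at 10.18 ± 1.90 and 26.03 ± 8.27, and GAREM2 at 1.97 ± 0.282 and 7.73 ± 3.78. The edgeR adjusted p was 0.981 for each of these 10 genes, and DESeq2 called 7 of them.

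For the EMT list, 31 of 36 measured members had a lower fitted value in knockdown and 5 a higher one, with a median log2 fold change of -0.84. None passed the edgeR test, over all genes or adjusted over the list alone. camera called the list lower (adjusted p = 1.49e-05), and the call was lost with an estimated correlation (adjusted p = 0.503 with an estimated correlation). The median ran from -1.36 without knockdown 2 to -0.57 without control 2, with the list called in both fits (camera adjusted p = 4.39e-05 and 0.037). Fibronectin (FN1) was at 285.9 ± 272.3 CPM in knockdown and 1223 ± 1633 in control (SD, n = 4 each), with the control mean set by 3671 CPM in control 2 against 345.6 to 485 in the other 3, and vimentin (VIM) at 105.2 ± 62.83 and 195.3 ± 83.42. The EMT transcription factors ZEB1, TWIST1, SNAI2 and SNAI1 had log2 fold changes of -1.03, -1.41, -0.47 and -0.46, with standard errors of 0.884, 0.949, 0.645 and 0.853, and ran with each library left out from -1.54 to -0.48, from -2.05 to -0.12, from -0.84 to -0.09 and from -0.86 to 0.20. ZEB1 and TWIST1 were nearest 0 without control 3, SNAI2 was so without control 2, and SNAI1 was above 0 without control 2. E-cadherin (CDH1) was at 618.6 ± 276.5 and 494.3 ± 384.8 CPM, and N-cadherin (CDH2) at 1.98 ± 3.04 and 2.46 ± 2.02. The hyaluronan receptor CD44 was at 778.5 ± 397.1 and 517.1 ± 285.4 CPM. With each library left out, log2 fold changes ran from 0.03 to 0.83 for CDH1, from -2.35 to 0.33 for CDH2, from 0.32 to 0.91 for CD44, from -3.00 to -0.50 for FN1 and from -1.32 to -0.63 for VIM.

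Matrix and stromal lists were called lower by camera with the preset correlation only. All 20 fibroblast markers, 4 of which are also in the EMT list, had a lower fitted value in knockdown (median -1.76, adjusted p = 7.98e-06, and adjusted p = 0.503 with an estimated correlation). The fibroblast markers COL6A3 and COL3A1 are also in the collagen list. COL6A3 was at 131.7 ± 52.06 CPM in knockdown and 581.5 ± 589.7 in control (1453 in control 2, and 184.7 to 427.2 in the other 3). COL3A1 was at 203.8 ± 42.05 and 1412 ± 2170 (4659 CPM in control 2, and 121.7 to 465.6 in the other 3 labelled control). Of 29 other collagen chains 22 were fitted lower (median -0.63, adjusted p = 0.0122, and 0.65 as adjusted p with an estimated correlation), with COL1A2 at 216 ± 48.09 and 1515 ± 2102 CPM (4652 in control 2, and 247.9 to 753.2 in the other 3). Of 31 collagen processing enzymes 26 were fitted lower (median -0.81, adjusted p = 6e-04, and adjusted p = 0.503 with an estimated correlation), among them CRTAP at a log2 fold change of -0.92 (SE 0.459), while P4HB was at 0.58 (SE 0.499). For matrix proteases and inhibitors the median was -0.69 (adjusted p = 0.029, and adjusted p = 0.682 with an estimated correlation), with the gelatinases MMP2 at -0.67 (SE 0.679) and MMP9 at -2.70 (SE 1.622). Cathepsin B (CTSB) stood at -1.05 (SE 0.782) and SERPINB5 at 1.14 (SE 1.097). For integrins and focal adhesion genes the median was -0.42 (adjusted p = 0.00963, and adjusted p = 0.682 with an estimated correlation), with filamin A (FLNA) at -1.35 (SE 0.863) and SDC1 at 0.59 (SE 1.166). For leukocyte markers it was -0.70 (adjusted p = 0.0302, and adjusted p = 0.682 with an estimated correlation), with CSF1R at -1.50 (SE 0.566) and LYZ at 0.26 (SE 2.404). Without control 2, which held the most COL1A1, the calls of other collagen chains, collagen processing enzymes, proteases, integrins and leukocyte markers were lost (camera adjusted p = 0.437, 0.178, 0.921, 0.651 and 0.912), and the medians of these 5 lists were 0.03, -0.48, -0.17, -0.04 and -0.15. Without it the log2 fold changes of COL1A2, COL3A1, COL6A3, MMP2, MMP9, CTSB and CSF1R were -1.12, -0.70, -1.14, -0.04, 1.42, -0.51 and -0.85. With each library left out, they ran from -1.84 to -0.59 (without control 4) for FLNA, from 0.07 (without knockdown 3) to 1.40 (without control 4) for SDC1, from 0.74 to 1.52 for SERPINB5, from 0.31 to 0.70 for P4HB and from -6.12 (without knockdown 2) to 6.00 (without control 1) for LYZ. The median of other collagen chains was -1.01 without knockdown 2. Without knockdown 4 the calls of other collagen chains, proteases, integrins and leukocyte markers were lost (camera adjusted p = 0.0554, 0.21, 0.0985 and 0.314), as were those of proteases without knockdown 2 (0.121), integrins without control 4 (0.0817) and leukocyte markers without knockdown 1 (0.0842). Scaling by library totals in place of TMM also ended the calls of proteases and leukocyte markers (camera adjusted p = 0.14 and 0.0705).

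The lists called higher by camera with the preset correlation were epithelial, metabolic and interferon genes, and all of these calls were also lost with an estimated correlation. Keratinocyte differentiation genes had 41 of 43 members fitted higher in knockdown (median 3.30, adjusted p = 1.05e-11, and adjusted p = 0.503 with an estimated correlation), with KRT14 at 20130 ± 21150 and 4153 ± 5074 CPM and KRT6A at 27330 ± 26660 and 6257 ± 7225 (log2 fold changes from 1.75 to 3.52 and from 1.64 to 3.00 with each library left out). Epithelial junction genes had 40 of 50 fitted higher (median 0.82, adjusted p = 2.27e-09, and adjusted p = 0.484 with an estimated correlation), with the desmosomal genes DSP at 1.46 (SE 1.296) and DSG3 at 0.46 (SE 1.68), which ran from 0.04 without control 1 to 1.46 without control 4. Adjusted over the list alone, ELF3 passed (edgeR adjusted p = 0.031). Cholesterol and fatty acid synthesis had 32 of 37 fitted higher (median 0.83, adjusted p = 7.35e-12, and adjusted p = 0.484 with an estimated correlation). The desaturase SCD was at 964.3 ± 472.7 and 161.7 ± 184.1 CPM, and TM7SF2 passed adjusted over the list alone (edgeR adjusted p = 0.0071). All 13 mitochondrial mRNAs were fitted higher (median 1.12, adjusted p = 6.95e-07, and adjusted p = 0.503 with an estimated correlation), MT-CO1 by 0.60 (SE 1.22; 0.28 to 1.17 with each library left out) and MT-ND4 by 1.19 (SE 0.888; 0.85 to 1.78). Interferon-stimulated genes had 43 of 46 fitted higher (median 1.24, adjusted p = 1.53e-05, and adjusted p = 0.682 with an estimated correlation), with SAMD9 at 522.5 ± 548.3 and 130 ± 188.9 (log2 fold change from 1.30 to 3.83 with each library left out). The interferon call was also lost without knockdown 1 or knockdown 3 (camera adjusted p = 0.0828 and 0.0859; medians 0.86 and 0.64), and the median was 2.34 without control 2. With the muscle share as a covariate, a fit added after seeing the data, the median was -0.30, though camera called the list higher (adjusted p = 0.00338). fry called 0 of the 24 lists, in the directional and in the mixed test.

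The other 12 lists were not called by camera, and 0 of their members passed the edgeR test over all genes or adjusted over the list alone. Their median log2 fold changes were -0.23 for TGF-beta signalling, -0.10 for YAP/TAZ targets, -0.07 for Wnt, MYC and PI3K members, -0.04 for NF-kB cytokines, -0.10 for p53 targets, 0.16 for the stress response list and -0.04 for hypoxia and glycolysis. They were 0.68 for replication-dependent histones (-0.02 without knockdown 1, 1.33 without control 2) and 0.24 for long noncoding RNAs (0.13 to 0.35 with each library left out, and 0.00 with library totals in place of TMM). For proliferation genes (0.02), immediate early genes (-0.23) and endothelial and mural markers (-0.07), the direction given by camera was opposite to the median, and for NF-kB and cytokine genes the mean (0.23) was opposite to both. Leaving out 1 library turned the sign of the median in 10 of the 12 lists. Immediate early genes had a median of 0.86 and were called higher without control 3 (camera adjusted p = 6.78e-06), which held 1.73% of counts in that list against 0.0764% to 0.247% in the other libraries labelled control; they were also called without knockdown 2 (median -0.06, adjusted p = 0.0392) and, in a fit added after seeing the data, without the libraries with over 1% of counts in muscle or salivary genes (0.73, adjusted p = 1.84e-06). Among single members, EGFR was at 1087 ± 1475 and 2813 ± 5044 CPM, FOS at 379.4 ± 287.1 and 904.9 ± 1547, and RN7SL1, the RNA of the signal recognition particle, at 65660 ± 58560 and 23490 ± 13040. EGFR had 10380 CPM in control 4 against 133.2 to 381.6 in the other 3 labelled control, and its log2 fold change was -1.37, or 1.91 without control 4. FOS had 3219 CPM in control 3 against 36.25 to 302.5, and its log2 fold change was -1.25, or 1.50 without control 3. RN7SL1 had 147900 CPM in knockdown 3 against 18830 to 66700 in the other 3 labelled knockdown, and its log2 fold change was 1.48, or 0.69 without knockdown 3. The glycolytic genes GAPDH and PKM had log2 fold changes of -0.54 (SE 0.55) and 0.05 (SE 0.599), and ran from -0.71 to -0.30 and from -0.37 to 0.32 with each library left out. Scaling by library totals in place of TMM moved the median of all genes from -0.05 to -0.21, and PKM and the median of proliferation genes (-0.25) were then negative.

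Fits added after seeing the data moved some values outside their ranges with each library left out. Without the libraries with over 1% of counts in muscle or salivary genes, the medians were 2.31 for mitochondrial mRNAs, -1.38 for the EMT list, -1.19 for collagen processing enzymes, -0.68 for integrins and focal adhesion genes and -0.49 for TGF-beta signalling. The log2 fold changes were then 1.87 for MT-CO1, 2.51 for MT-ND4, -3.28 for CDH2, -1.65 for CRTAP, -0.20 for GAPDH and -0.71 for PRKAB2, which was at -1.35 with all libraries. This fit held only knockdown 1 and 3 and controls 2 and 4. The CDH2 value rests on 5.07 CPM in control 2, against 0.23 in control 4, 0.51 in knockdown 1 and 0 in knockdown 3. With the muscle share as a covariate, the medians were -1.09 for fibroblast markers, 2.74 for keratinocyte differentiation genes and 0.37 for endothelial and mural markers, which camera then called higher (adjusted p = 0.0233). The log2 fold changes were then 0.04 for ZEB1, -0.57 for VIM, 0.18 for CD44, 0.46 for SERPINB5, 0.42 for KRT14, 1.25 for KRT6A and 0.32 for SAMD9.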

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

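The tests of muscle and salivary RNA, of COL1A1 and of the edgeR calls against other splits were chosen after the results were seen; those of DESeq2 and of the gene lists against other splits were set before. In 188 tests of a group of 4 for a single library far from the other 3, 17 passed the limit (9.0%), where chance gives about 1 in 20. Knockdown 2 accounted for 8 of them. It held less of the epithelial junction list (0.677% of counts against 3.07% to 4.08% in the other libraries labelled knockdown) and of keratinocyte differentiation genes (0.447% against 15.3% to 25.6%). Its CPM was lower for SPRR2E (2.48 against 871 to 1400), DSG3 (17.4 against 2700 to 5680), NFKBIA (69.0 against 245 to 266) and H2AC6 (29 against 92.6 to 103). It was higher for LYZ (12600 CPM against 21.3 to 50.2), and with it for the leukocyte list (1.44% of counts against 0.0101% to 0.0184%), in which LYZ is also a salivary gland gene.

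Control 2 stood above the other libraries labelled control for FN1 (3670 CPM against 346 to 485) and H1-2 (81.8 against 38.8 to 42.9). Control 1 held 22.4% of counts in salivary gland genes against 0.00839% to 0.0223%, and 0.0218% in proliferation genes against 0.115% to 0.15%. Control 3 was low for P4HB (204 CPM against 638 to 677) and for long noncoding RNAs (1.57% of counts against 3.77% to 3.87%), though without the 3 most abundant genes of that list it was the highest of the 4 (0.139% against 0.0887% to 0.118%). Control 4 was high for GAREM2 (13.4 CPM against 5.53 to 6.34). Knockdown 1 held 0.783% of counts in mitochondrial mRNAs against 3.61% to 4.15%, and knockdown 3 held 0.12% in YAP/TAZ targets against 0.155% to 0.156%.

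Transcripts of skeletal muscle and salivary gland in libraries labelled as a carcinoma line are the first pattern. A change brought by the siRNA is argued against, because the muscle list took 17.86% of counts in the highest library labelled control and 0.035% in the lowest, and 5.55% and 0.02% under the knockdown label. A few genes gathering stray reads are also argued against, since without its 3 most abundant genes the muscle list still took 6.02% of counts in 1 library. A candidate explanation is RNA of skeletal muscle tissue in some libraries: 100.0% of the 39 muscle genes with at least 80 counts followed the rest of their list (median rho 0.95), including all 35 that had not been looked at when the list was written. For salivary gland the share was 63.9% of 36 genes. This share lay between the limits for and against, so the test does not decide. The salivary list took at most 0.052% of counts outside control 1 and knockdown 2, and these libraries differed in its genes. In CPM of all counts, LCN1 was at 66000 in control 1 and 0.391 in knockdown 2, BPIFA1 at 48200 and 2.93, and MUC5B at 3950 and 60200. DMBT1 (19700 and 2300) and LYZ (9060 and 14100) were high in both. Without its 3 most abundant genes that list still took 10.61% of counts in control 1 and 9.17% in knockdown 2. A few genes gathering stray reads are thus argued against here too. Whether muscle or gland RNA came from tissue, from other samples or from libraries exchanged with another study has no test in these data. The labels name no tissue. Genes of other cell types were present in all 8 libraries, also in those with the least muscle RNA. In CPM of all counts, the leukocyte gene PTPRC was at least 11, the endothelial gene PECAM1 at least 32.0 and the fibroblast gene DCN at least 27.5. As far as these genes show, the values argue against RNA of a carcinoma line alone in any library. Contrasts in EMT, collagen and leukocyte genes thus cannot be read as responses of HSC3 cells alone.

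The overlap of COL1A1 between labels is the second pattern. A loss of COL1A1 apart from other fibrillar collagens stays open, because the log2 ratio to COL1A2 differed by 0.33 with an interval from -1.42 to 2.5, which includes a halving on the log2 scale (-1). Stromal content of each library may account for part of the COL1A1 level: across the 8 libraries COL1A1 had Spearman rho = 0.57 with COL1A2 (exact permutation p = 0.15, adjusted 0.15; Pearson r = 0.88, exact permutation p = 0.018, adjusted 0.018) and rho = 0.88 with COL3A1 (exact permutation p = 0.0072, adjusted 0.014; r = 0.96, exact permutation p = 0.0012, adjusted 0.0024), for 2 relations tested. Without the 2 libraries farthest from the median of COL1A2 or of COL3A1, r was 0.49 and 0.75. Leaving out the ends of the range tends to lower r. Whether the relation with COL1A2 rests on those libraries thus stays open. Both correlated genes are collagens, and other fibroblast markers were divided. In CPM of all counts, DCN, C3 and FBLN1 were at 1270, 1110 and 377 in control 3. They were at 151, 303 and 61.9 in control 2, which held the most COL1A1. PDGFRB was at 157 in control 3 and 171 in control 2, so stromal content stays open. A swap of 1 knockdown and 1 control label cannot be told apart from the labels as given. Of the 16 single swaps, 1 separated the groups in COL1A1 CPM of all counts and 0 did so in TMM CPM. At most 1 swap can do so for any set of distinct levels, so this count decides nothing. The scalings differ because knockdown 3 and control 3 were nearly tied in TMM CPM (402 and 401.3). After the swap that separated the groups, edgeR called 0 genes, DESeq2 319 against 146 for the labels as given, and camera 16 lists against 12. Genes at an unadjusted p under 0.05 then numbered 1518 against 1013.

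The number of calls is the third pattern. Over the 35 splits of the 8 libraries into 4 and 4, chance cannot be excluded for the counts of DESeq2 and of camera. For the edgeR counts the comparison decides nothing, because no split can call fewer than 0: edgeR called 0 genes in the labelled split and 2189 in the highest other, and 0 against 2143 at 2-fold, and 35 of 35 splits gave as many. DESeq2 called 146 in the labelled split and 5603 in the highest other, and 13 splits gave as many; camera called 12 lists against 19, and 15 splits gave as many. The split with 2189 calls, the only split with any edgeR call, sets knockdown 1, knockdown 3, control 2 and control 4 against the rest. Skeletal muscle genes took 0.02% to 0.53% of counts in the named libraries and 4.31% to 17.86% in the rest. The named libraries also had the positive scores on the first principal component, and the rest the negative ones. That grouping thus goes with muscle transcripts and not with the labels, and the cause of the calls was not tested.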

How the results depend on the processing

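The count of 0 called genes, with or without the 2-fold limit, was also 0 under limma-voom, RLE factors, library totals, both other filters, and without genes over 1% of counts. With DESeq2 it was 146 for both counts. The cause was not tested, though DESeq2 called 90 unchanged genes in simulated counts with the real spread. Those counts held only genes kept by the filter of the edgeR fit, which had removed 44 of the 146. Leaving out each library gave 0 to 1 called genes; the 1 gene, without knockdown 2, was SPRR2F. In fits added after seeing the data, edgeR called 1 gene, again SPRR2F (adjusted p = 0.00857), without the libraries with over 1% of counts in salivary genes, 0 without those over 1% in muscle or salivary genes (2 libraries per label), and 0 with the muscle share as a covariate. Genes at an unadjusted p under 0.05 numbered 1013, 1972 with DESeq2, 2067 with no filter, 609 to 1713 with each library left out, 2366 without the libraries over 1% in muscle or salivary genes, 1713 with the muscle covariate, and 352 with a replicate block, which called 0 genes and 14 lists. Same-numbered libraries did not deviate together (correlations -0.70, -0.49, -0.37 and -0.38). The highest correlation, 0.71, was that of knockdown 2 with control 1, both rich in salivary gland transcripts. Such differences could hide a shared culture or day, so whether the numbers pair the libraries is unknown. COL1A1 had a log2 fold change of -1.24 under the block.

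The log2 fold change of COL1A1 was negative with an adjusted p above 0.05 in every alternative run, and ran from -3.38 to -0.48 with each library left out. Of 66 other named genes in 1247 refits, 7 became called, all with DESeq2, and 65 values changed sign. The 12 lists called by camera became 0 with an estimated correlation and 0 with fry. Over 384 refits of the 24 lists, 24 calls were gained, 40 lost and 3 reversed in direction; the reversed lists had not been called before. Those were NF-kB cytokines (median 0.62) without the libraries over 1% in muscle or salivary genes, proliferation (0.37 without knockdown 2, range -0.74 to 0.37 with each library left out), and endothelial and mural markers (-0.33 without control 4, range -0.38 to 0.27); the cause was not tested. The first component took 52.1% of the variance over all filtered genes and 57.2% to 73.2% with each library left out. Depth was at least 30684584 counts per library, and the spread between libraries (biological coefficient of variation 0.79), not counting error, limited the tests.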

Other observations

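Cell type transcripts beyond the comparison also varied between libraries of a label. NEB, a sarcomere protein, ran from 5.0 to 14800 CPM of all counts, the slow myosin MYH7 from 0.327 to 16400 and creatine kinase CKM from 0.274 to 5520. BPIFA1, an airway and salivary secretory protein, ran from 0.0647 to 48200. KRT4, a keratin of moist stratified epithelium, was highest in knockdown 4 at 45300 CPM of all counts and lowest in knockdown 2 at 4.79. The smooth muscle myosin MYH11 stood at 792 in knockdown 2 and 735 in control 1 and at most at 53.4 in the others. Smooth muscle genes took 0.0155% to 0.715% of counts and adipocyte genes 0.005% to 0.0877% (exact permutation p = 0.286 and 0.0571 between labels, adjusted p = 0.659 for both over 28 lists), and both lists were written after the counts had been seen. Of the 39 skeletal muscle genes, 12 stood at 1 CPM of all counts or more in knockdown 3, where the list was lowest, as did 9 of the 38 salivary gland genes in control 3. DES among the muscle genes and LYZ among the salivary genes are also in another list.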
